A study of Mus musculus with 16 samples.

How the data were processed

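The series holds 16 samples of single-cell RNA sequencing, 4 for each of skin, lung, liver and draining lymph node, from mice aged 16 weeks. The titles of the 4 samples of a tissue differ only in an ending from L001 to L004, the form of flow cell lanes, and nothing in the labels calls them separate animals, so each tissue was treated as 1 library. Per the labels' protocols, the lymph node was dissociated mechanically, skin was minced and digested with collagenase IV and DNase, lung was digested with Liberase and DNase, and liver was mashed and digested with collagenase IV and DNase. Lung and liver cells also passed a Percoll gradient, per the same protocols. The series describes the cells as CD8+Thy1.1+, and how they were isolated is not given in the sources used here.

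The authors deposited 1 table of whole-number counts with 9223 genes and 5727 cells. Per the submitters' processing notes, reads were aligned with Bowtie and quantified with RSEM against mm10, with no versions given. Whether the counts are of unique molecular identifiers is not given in the sources used here, although the barcodes have 16 bases. Column names carry the tissue, and 0 columns were left without a tissue. The names of skin and lymph node cells have a 2 after the tissue and those of lung and liver cells do not. What the 2 marks, such as another library, run or chemistry, is not given in the sources used here. Genes are named by symbol only, and list members were matched to the table through older symbols where needed. The filters by which the authors chose genes and cells are not given in the sources used here.

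Cells were kept with at least 500 counts, 200 genes and at most 10% of counts from mitochondrial genes, which removed 0 cells. No cluster was led by markers of another cell class, and none was left out. Scrublet, run per tissue with an expected rate of 0.05, called 27 doublets in skin, 10 in lung, 17 in liver and 8 in lymph node, 62 in all (1.08%). They were kept in the main values and left out in an alternative. The summed counts were 3292210 for skin, 8072278 for lung, 1928185 for liver and 4532333 for lymph node.

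Cells are not replicates, so counts were summed per tissue and divided by the tissue's total over the listed genes to give counts per 1000000 (CPM). Ratios of 2 tissues carry the exact 95% interval for a ratio of Poisson counts, from the conditional binomial, and shares of cells carry the Clopper-Pearson interval. Both cover counting error only. With 1 library per tissue no test was made and no p-value is given. A gene with 0 counts in a tissue was set at 3 counts over that tissue, and its ratio is a lower bound.

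The lists, markers, comparisons and a first set of genes for shares of cells were chosen before the data were examined. Shares of Ccl1, Xcl1, Nr4a1, Fos, Top2a, Cd8a, Cd3e, Thy1 and Trdc were not in that set. Background was planned to be shown by genes of other cell types, but the choice of Lyz2, Scgb1a1, Igkc and Cd79a was not set beforehand. For skin, lung and liver over lymph node, the 12 genes in each direction with the interval bound farthest from equality were named, among genes with at least 50 CPM and a count in 10% of cells in the higher tissue. Between peripheral tissues the number was 8. Ribosomal, mitochondrial, T cell receptor, immunoglobulin and predicted genes were left out of that rule, and any member of a list, marker set or share could also be named. For each of 16 lists, the median log2 ratio was taken over members with a summed count of at least 20 in the 2 tissues. Its percentile was taken among 10000 random lists of the same size, matched on mean expression in 20 bins. The lists cover tissue residency, recirculation, central memory and stemness, cytotoxic effectors, chemokines, chemokine receptors and integrins, inhibitory receptors and exhaustion, immediate early genes, heat shock, interferon stimulated genes, proliferation, lipid metabolism, glycolysis, TGF-beta response, the TNF superfamily with costimulation, and T cell identity.

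Shares of cells with a count of a gene were taken after each cell was thinned to 1886 counts, the 10th percentile over all cells. This left out 141 skin, 273 lung, 27 liver and 131 lymph node cells below that depth, among them 160 of the 296 lung cells of cluster 6. Clusters came from log-normalized counts, 2000 variable genes without receptor segments, 30 principal components, 15 neighbors and the Leiden method at resolution 0.6, without integration. A cluster was named only where at least 3 of its fixed markers were detected and its leading genes did not go against the name, and clusters that followed a library were given by number. Within a cluster, tissues were compared where at least 50 cells of each were present. Positions came from GENCODE M21 on GRCm38, the assembly also called mm10, where 340 of 348 symbols looked up had a single position.

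The ratio procedure was tested on simulated counts with known fold changes. For skin over lymph node (8953 genes), 54.4% of genes changed 1.5-fold, 88.5% of those changed 2-fold and 100% of those changed 4-fold had an interval that excluded equality. The shares were 64.9%, 89.7% and 100% for lung (9031 genes) and 60.9%, 85.9% and 98.5% for liver (8828 genes). Intervals held the true ratio for 95.6%, 95.8% and 95.4% of genes. The simulated counts were Poisson counts, the model that the intervals assume, so this coverage was fixed in advance. It does not carry over to genes whose counts sit in few cells, such as Xcl1 in skin.

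Alternatives covered the scaling of counts, the summary over cells, the minimum count of list members, the cells kept, the thinning depth, the minimum count of a positive cell, and the clustering settings. Others were added after the data were seen, namely residency without members that stimulation raises, the lymph node without its central memory-like cells, totals and correlations without predicted genes and pseudogenes, a clustering of lymph node cells alone, and ratios and list medians without the cell of highest count. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, igraph 0.11.9 and matplotlib 3.10.9.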

Results

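Single-cell RNA sequencing measured gene expression in Pmel T cells, CD8+ T cells that carry a transgenic receptor for the melanoma antigen gp100 and the marker Thy1.1. The cells came from C57BL/6 mice with melanoma-associated vitiligo, an autoimmune loss of pigment cells, 45 days after tumor surgery. Skin, lung, liver and the draining lymph node each gave 1 library, so no value has a replicate and no difference was tested. The deposited table held 1224 cells from skin, 2322 from lung, 556 from liver and 1625 from lymph node. Their summed counts were 3292210, 8072278, 1928185 and 4532333, and the median counts per cell were 2518, 2943, 3096 and 2649. Levels are given as counts of a gene per 1000000 counts of a tissue's pooled cells (CPM). Every interval is an exact 95% interval that covers counting error only, not differences between mice or between libraries. Genes of myeloid cells, B cells and airway epithelium were detected in up to 5.37% of lung cells, 2.08% of liver cells, 1.87% of lymph node cells and 0 skin cells at equal depth. Some ratios had a lower level from a share of cells below this, or with an interval that held it. Such a level is not shown to be above background, and the ratio may be a lower bound. The background of each gene itself was not measured. For skin the level of 0 is not a bound, because no gene of the skin's own cells was used. Of 8 keratinocyte markers 2 were in the table, but their shares at equal depth were not taken. Ratios with skin as the lower level may therefore also be lower bounds.

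Across 7480 genes with at least 10 CPM in any tissue, lung and liver were the most alike pair, with a Spearman correlation across genes of 0.965. Lung and lymph node followed at 0.904, skin and lymph node at 0.886, liver and lymph node at 0.883, skin and liver at 0.869, and skin and lung at 0.854. Genes are not independent replicates, so no p-value belongs to these correlations. The libraries also differed by a measure that is not T cell biology. The 14 listed pseudogenes whose names end in -ps summed to 7766 CPM in skin and 7074 in lymph node, against 2149 in lung and 2102 in liver. Relative to their parent genes, 13 of the 14 were lower in lung than in lymph node, with a median log2 difference of -1.89. The corresponding medians were -1.82 for liver over lymph node, 0.44 for skin over lymph node and 0.07 for lung over liver. The names of the deposited cells split the same way, with an unexplained 2 after the tissue for skin and lymph node only. Comparisons of lung or liver with skin or lymph node therefore ran across this difference between libraries. Skin and lymph node also differed, by less, with 13 of the 14 ratios higher in skin, and 9 of 14 were higher in lung than in liver.

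**Figure D1:**
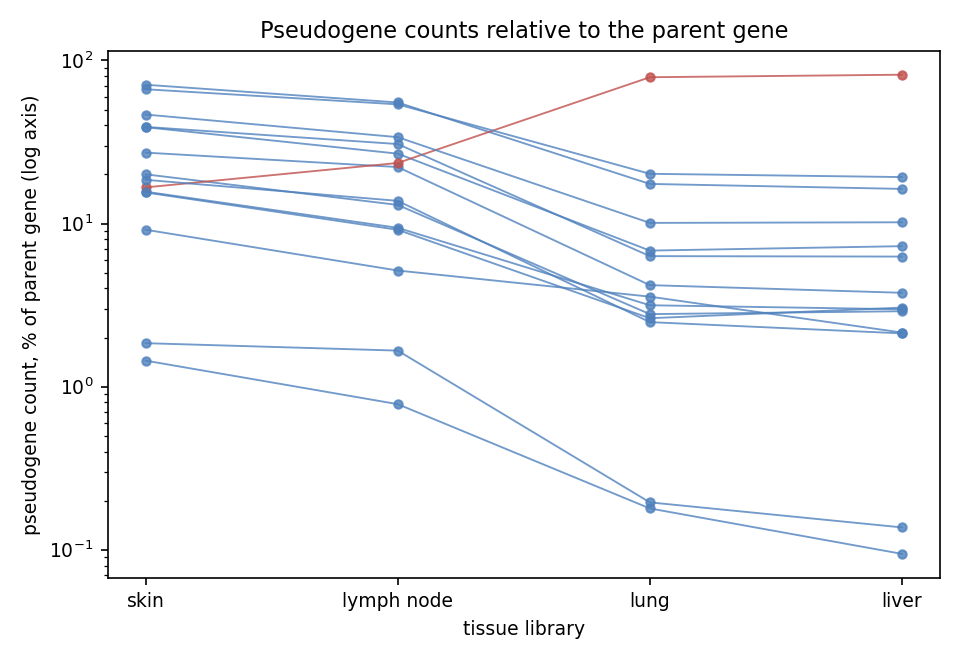
Counts of 14 pseudogenes as a percentage of the counts of their parent gene (log axis) in each tissue library; each line is a pseudogene. The lines drop between lymph node and lung for 13 of the 14 pseudogenes (blue) and climb for 1 (red).

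The comparison of skin with the draining lymph node asked how tumor-specific memory cells at the site of autoimmunity differed from those in the node. Skin cells held high levels of immediate early, chemokine and tissue residency genes, and low levels of recirculation, central memory and interferon stimulated genes. Nr4a1, an immediate early gene induced by T cell receptor signaling, was 117-fold higher in skin (95% interval 89.6 to 156), at 1395 CPM against 11.9. Its share of lymph node cells, 1.81%, lay at the background level, so the ratio may be a lower bound. Ccl1, which encodes a chemokine ligand of CCR8, was 114-fold higher (89.3 to 147), at 1658 CPM against 14.6. A single lymph node cell held 38 of the 66 counts of Ccl1 there, and without it the ratio was 268. A single skin cell held 1410 of its 5457 counts in skin, and leaving out that cell instead would lower the ratio. Ifng, the gene of interferon gamma, was 13.1-fold higher (12.2 to 14.1), and Cd69, whose product retains cells in tissue by opposing S1PR1, was 6.47-fold higher (5.83 to 7.19).

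Of the 33 measured members of the tissue residency list, 24 were higher in skin than in lymph node, 20 of them with an interval that excluded equality, and 9 were lower. The list's median log2 ratio was 0.66, above every one of 10000 random lists matched on expression (95% range -0.28 to 0.10). Xcl1, a chemokine gene, was 14.8-fold higher in skin (13.1 to 16.7), and 9.18-fold higher without the single skin cell that held 1241 of its 3254 counts. Rgs2 and Litaf were 6.47-fold and 4.26-fold higher. Itgae, which encodes CD103, a receptor for epithelial E-cadherin, stood at 542 CPM in skin and 373 in lymph node, a ratio of 1.45 (1.36 to 1.55). Cxcr6, a chemokine receptor gene of resident cells, was higher in the lymph node, by 1.46-fold (1.41 to 1.52). Without the 12 residency members that T cell stimulation also raises, Cd69 and Xcl1 among them, the median log2 ratio was 0.21, and with members of at least 100 counts it was 1.21. In GRCm38 (mm10), Itgae lies on chromosome 11 from 73090583 to 73147446 and Cd69 on chromosome 6 from 129267325 to 129275436.

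Of the 18 measured recirculation genes, 16 were lower in skin, with a median log2 ratio of -1.09, below every random list. The fixed markers of circulating effector memory cells did not follow, with 3 of 6 higher in skin and 3 lower. Their median log2 ratio was 0.44, above the random range of -0.50 to 0.38. Klf2, a transcription factor gene of circulating T cells (chromosome 8, 72319033 to 72321656), was 2.06-fold lower (1.84 to 2.30). S1pr1, its target and the receptor by which T cells leave tissue, stood at 5.47 CPM in skin and 15.4 in lymph node. Its share of lymph node cells lay next to that of Igkc, a B cell gene. Part of that level may be background, so no direction is read. Among the 14 central memory and stemness genes, 12 were lower (median log2 ratio -0.89). Il7r, the gene of the interleukin-7 receptor chain, was 6.08-fold lower (5.31 to 6.98), Slamf6 was 12.9-fold lower (6.37 to 30.4), and Tcf7 was 1.65-fold lower (1.31 to 2.08).

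Immediate early genes were higher in skin for 22 of 23 members, with a median log2 ratio of 2.73. Fosb was 25.7-fold higher (19.3 to 35.0), Atf3 50.2-fold, Fos 13.4-fold and Egr1 10.6-fold, while Jun was 2.63-fold lower (2.18 to 3.18). Other genes that met the naming rule were Nr4a3, 56.6-fold higher (32.1 to 110), and Cdkn1a, which encodes the cell cycle inhibitor p21 and was 36.9-fold higher. Gadd45b was 30.6-fold, Tppp3 34.4-fold, Hk2 22.9-fold, Crem 18.9-fold, Phlda1 17.8-fold and Nfkbid 16.3-fold higher. Heat shock genes were higher for 10 of 12 members (median log2 ratio 0.76), with Hspa1a at 3.48-fold. The protocols in the labels differed between the tissues, since skin was minced and digested with collagenase and the lymph node was dissociated mechanically.

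Chemokine genes were higher in skin for 5 of 6 members (median log2 ratio 3.19), with Ccl3 at 14.4-fold, and the exception was Ccl5, 1.80-fold lower (1.77 to 1.82). Cytotoxic effector genes were higher for 13 of 18 (0.52), including Tnf at 8.33-fold, while Gzmb differed by 1.03-fold with an interval (0.981 to 1.08) that held equality. Its share of cells at equal depth did differ, at 36.3% of skin cells (33.4 to 39.2) and 51.7% of lymph node cells (49.2 to 54.3). Of 13 inhibitory receptor and exhaustion genes, 8 were higher (1.15), among them Nr4a2 and Nr4a3, relatives of the immediate early gene Nr4a1. Pdcd1, the gene of PD-1, was 9.54-fold higher (7.92 to 11.6) at 272 CPM, and Tox, a transcription factor gene of exhausted cells, was 1.61-fold lower (1.13 to 2.32). TGF-beta response genes were higher for 10 of 13 (0.79), with Tgif1 at 13.2-fold and Skil at 5.50-fold. Genes of the TNF superfamily and costimulation were higher for 9 of 14 (0.33), with Tnfrsf9, the gene of 4-1BB, at 10.9-fold and Tnfsf8 2.88-fold lower. Each of these medians lay outside the 95% range of matched random lists. The fixed markers of exhausted cells did not differ beyond that range, with 4 of 6 lower in skin (median log2 ratio -0.35).

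Proliferation genes were higher in skin for 21 of 22 members (median log2 ratio 1.31), with Stmn1 at 4.86-fold, Mki67 at 2.78-fold and Ube2c at 9.41-fold. Glycolysis genes were higher for 12 of 16 (0.95), with Ldha at 2.10-fold, and genes of lipid uptake and metabolism for 11 of 14 (0.65), with Insig1 at 5.10-fold. Chemokine receptor and integrin genes were higher for 6 of 17 (-0.27) and T cell identity genes for 7 of 12 (0.02), both within the range of random lists. Cxcr3 was 3.12-fold and Ccr2 2.30-fold lower in skin. All 21 measured interferon stimulated genes were lower in skin (median log2 ratio -1.69), below every random list. Among them Ifit1 was 6.97-fold lower (5.48 to 8.98), Rtp4 5.80-fold and Irf7 2.81-fold. Over all tissues, Ifit1 stood at 1210.5 CPM in the interferon responding-like cluster 7, described below, and 29.9 in the other cells. That cluster held 8.12% of lymph node cells and 0.490% of skin cells, and no ratio was taken without it. Ifit1bl1 at 15.2-fold and Ifit3 at 8.83-fold share sequence with relatives, which leaves their values uncertain. Other genes named by the rule as lower in skin were Slfn1 (10.2-fold), BC094916 (7.05-fold), Ifi47 (5.27-fold), Plekhf1 (4.81-fold), Gimap4 (4.73-fold), Il16 (4.38-fold) and Pyhin1 (4.07-fold).

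**Figure D2:**
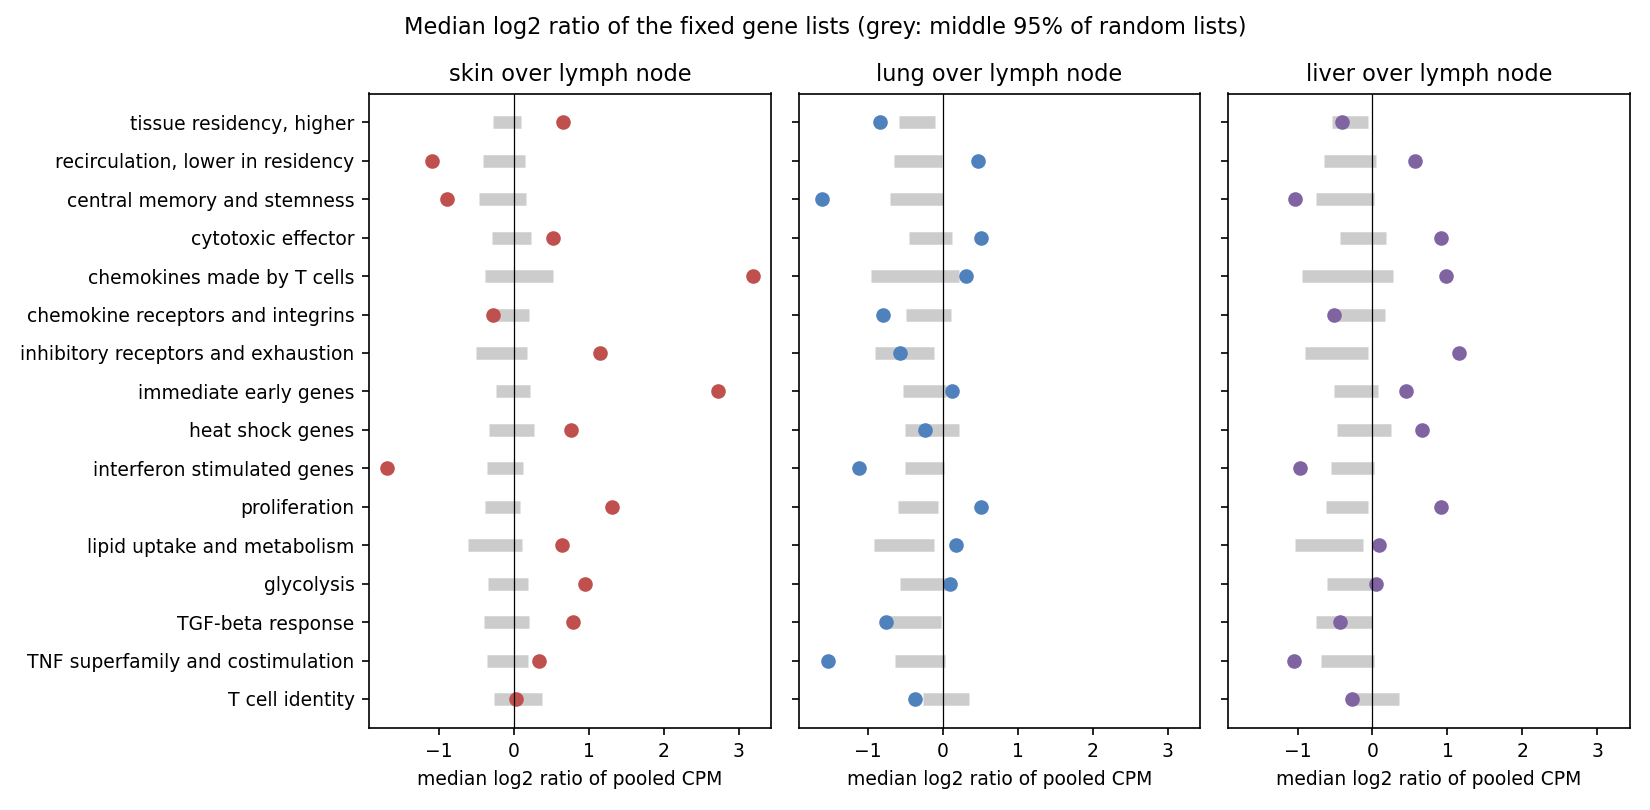
Median log2 ratio of pooled CPM over the lymph node for each gene list in skin, lung and liver, with the 95% range of 10000 random lists matched on expression. The immediate early list stands at 2.73 in skin against 0.12 in lung and 0.44 in liver, and the recirculation list at -1.09 in skin against 0.47 and 0.56.

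The comparison of lung with lymph node asked the same of a peripheral organ away from the autoimmune site. Lung cells held high levels of recirculation and cytotoxic genes and low levels of residency, central memory, costimulation and interferon stimulated genes. Ly6c2, a marker of circulating memory and effector cells, was 23.8-fold higher in lung (21.2 to 26.8), at 1560 CPM against 65.5, although it shares sequence with other Ly6 genes and its value is uncertain. Gzma, the gene of granzyme A, was 21.2-fold higher (20.4 to 21.9), and Klf2 was 4.04-fold higher (3.80 to 4.28). S1pr1 was higher by a ratio of 6.43 (5.03 to 8.34), which may be a lower bound because part of its lymph node level may be background. Tcf7, the gene of TCF-1, a factor of stem-like memory cells, was 8.38-fold lower (6.22 to 11.5), at 6.69 CPM against 56.0. This may also be a lower bound, since its share of lung cells, 1.42%, lay below the background level.

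Of 22 measured recirculation genes, 15 were higher in lung, with a median log2 ratio of 0.47 (random 95% range -0.66 to -0.02), above every random list. The median was 1.16 with members of at least 100 counts, 0.87 under size factors, 0.87 without the central memory-like lymph node cells and 0.76 without cycling cells. Rasgrp2 was 3.64-fold higher (3.27 to 4.06), Itgb1 3.03-fold and S1pr4 2.23-fold. Of 33 residency genes, 28 were lower (median log2 ratio -0.85, random range -0.58 to -0.10), below every random list, and the median was -0.45 under size factors. Itgae was 1.95-fold lower (1.82 to 2.10), Cxcr6 1.84-fold, Xcl1 7.39-fold (5.71 to 9.68) and Isg20 4.98-fold, while Cd69 was 1.34-fold higher (1.19 to 1.5). Central memory genes were lower for 12 of 14 (-1.62), with Slamf6 at 11-fold and Il7r at 3.56-fold. The pseudogene counts separated these libraries as well.

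Cytotoxic effector genes were higher in lung for 13 of 19 members (median log2 ratio 0.50), with Gzmk at 5.55-fold (4.94 to 6.26) and Ifng at 2.31-fold (2.14 to 2.5). Chemokine genes were higher for 4 of 7 (0.31), with Ccl5 at 2.76-fold (2.73 to 2.78) and Cxcl10 4.86-fold lower. Proliferation genes were higher for 16 of 22 (0.51), with Ube2c at 9.80-fold, although Mki67 differed by 1.04-fold with an interval (0.716 to 1.48) that held equality. Immediate early genes were higher for 13 of 23 (0.12, and 0.27 to 0.52 under 3 alternatives), lipid genes for 9 of 13 (0.17) and glycolysis genes for 10 of 16 (0.09). These medians lay above the random ranges, which were centered below 0. All 14 genes of the TNF superfamily and costimulation were lower (-1.54), with Tnfsf8 at 33.5-fold (18.8 to 65.9) and Tnfrsf9 at 7.89-fold. Interferon stimulated genes were lower for 20 of 21 (-1.12), with Isg15 at 4.02-fold, and TGF-beta response genes for 11 of 13 (-0.77), with Skil at 2.27-fold. Chemokine receptors and integrins were lower for 10 of 18 (-0.80), with Ccr8 at 13.0-fold (7.69 to 23.5).

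Inhibitory receptor genes were lower in lung for 8 of 12 (median log2 ratio -0.58) and heat shock genes for 9 of 12 (-0.24), both within the random range. T cell identity genes were lower for 10 of 12 (-0.38). The heat shock and identity medians turned positive under size factors from median ratios, which moved the median of all genes by 0.40. Cd160 was 20.6-fold lower (12.9 to 34.9), or 32.6-fold without the lung cell that held 7 of its 19 counts there, Tox 14.2-fold and Cd8a 2.56-fold. Genes named by the rule as higher in lung were Tppp3 (116-fold, 68.9 to 212), Nacc2 (45.6-fold), Fcgrt (26.4-fold), Fxyd4 (26.0-fold), Itgax (25.4-fold), Ggt1 (17.9-fold), Nccrp1 (17.8-fold) and Ifitm1 (12.7-fold). The metallothionein genes Mt2 and Mt1 were 17.0-fold and 11.9-fold higher. Those named as lower were Lrch4 (7.78-fold), Ccdc85b (7.75-fold), Gbp9 (6.73-fold), Lpar6 (6.03-fold), Clec2d (5.46-fold), Ifit3 (5.28-fold), Grcc10 (5.05-fold) and Lrrc58 (4.55-fold). Gstp1, lower by 14.0-fold, has near-identical copies and is uncertain. So is AY036118, lower by 23.7-fold, which overlaps the predicted gene Gm42418 on the other strand and split the libraries as the pseudogenes did.

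The comparison of liver with lymph node put the same question to another peripheral organ. Liver cells shared the high recirculation and cytotoxic levels of lung, and also held high levels of heat shock genes and of some inhibitory receptor genes. S1pr1 was 9.30-fold higher in liver than in lymph node (7.13 to 12.3), at 144 CPM against 15.4, which may be a lower bound as for lung. Klf2 was 5.85-fold higher (5.48 to 6.25). Ctla4, which encodes an inhibitory receptor, was 17.0-fold higher (12.2 to 24.1), and Pdcd1 was 5.41-fold higher (4.39 to 6.71). Itgae was 2.09-fold lower (1.86 to 2.35) and Cd69 differed by 1.02-fold, with an interval (0.851 to 1.21) that held equality.

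Of 19 measured recirculation genes, 14 were higher in liver (median log2 ratio 0.56, random 95% range -0.65 to 0.05), above every random list, and the median was 1.08 with members of at least 100 counts, 0.996 under size factors and 0.91 without the central memory-like lymph node cells. Of 32 residency genes, 24 were lower (-0.40), within the random range of -0.55 to -0.06; the median was 0.03 under size factors from median ratios, the opposite sign. Without the members that stimulation raises it was -1.17. Cytotoxic genes were higher for 15 of 19 (0.92), with Gzma at 16.0-fold, Serpinb9, an inhibitor of granzyme B, at 20.5-fold and Gzmb at 1.92-fold. Inhibitory receptor genes were higher for 7 of 13 and lower for 6 (1.15), with Nr4a2, a relative of the immediate early gene Nr4a1, at 4.78-fold and Tox 7.37-fold lower (3.28 to 20.6). The fixed markers of exhausted cells were lower for 4 of 6 (-0.55), within the random range of -1.13 to 0.15. Chemokine genes were higher for 5 of 7 (0.98), with Ccl5 at 3.02-fold and Ccl3 at 1.98-fold, or 1.27-fold (0.95 to 1.68) without the liver cell that held 44 of its 122 counts there. Heat shock genes were higher for 11 of 12 (0.66), with Hspa1a at 2.73-fold and Hsp90aa1 at 2.43-fold. Proliferation genes were higher for 19 of 22 (0.91), with Birc5 at 6.18-fold, and immediate early genes for 12 of 22 (0.44, and 0.18 or 0.87 under 2 alternatives), with Nr4a1 at 14.0-fold (10.5 to 19.1) and Junb 2.69-fold lower. Pseudogene counts differed between these libraries in the same direction as for lung.

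Central memory genes were lower in liver for 12 of 14 (median log2 ratio -1.03), with Tcf7 at 3.38-fold (2.33 to 5.04) and Il7r at 3.04-fold. Interferon stimulated genes were lower for 20 of 21 (-0.97), with Irf7 at 1.55-fold. Genes of the TNF superfamily and costimulation were lower for 11 of 14 (-1.04), with Tnfsf8 at 8.01-fold. Chemokine receptors and integrins were lower for 9 of 17 (-0.51), though Cxcr4 was 7.60-fold higher (5.52 to 10.6). Lipid genes were higher for 8 of 13 (0.08), above the random range, and glycolysis genes for 9 of 16 (0.05), within it. TGF-beta response genes were lower for 9 of 13 (-0.43), within the random range, and T cell identity genes for 10 of 12 (-0.27), also within it. These last 2 medians turned positive under the size factors, whose shift of all genes was 0.43.

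Genes named by the rule as higher in liver were Tppp3 (87.0-fold), Fcgrt (21.4-fold), Fxyd4 (21.3-fold), Ly6c2 (21.2-fold), Itgax (19.4-fold), Ggt1 (16.1-fold), Serpinb6b (12.1-fold) and Ifitm1 (9.87-fold). Of these, Tppp3, Fcgrt, Fxyd4, Ly6c2, Itgax, Ggt1 and Ifitm1 were also named for lung. Those named as lower were Ccdc85b (25-fold, 9.63 to 92.5), Lrch4 (14.4-fold), Lpar6 (8.55-fold), Jun (7.15-fold), Samd9l (5.20-fold), Clec2d (5.04-fold), Grcc10 (5.03-fold), Lrrc58 (4.88-fold) and Isg20 (4.65-fold). Gstp1 (19.2-fold) and Psme2b (5.10-fold) were lower as well and have near-identical copies, so their values are uncertain, as is that of AY036118 (30.4-fold lower).

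**Figure D3:**
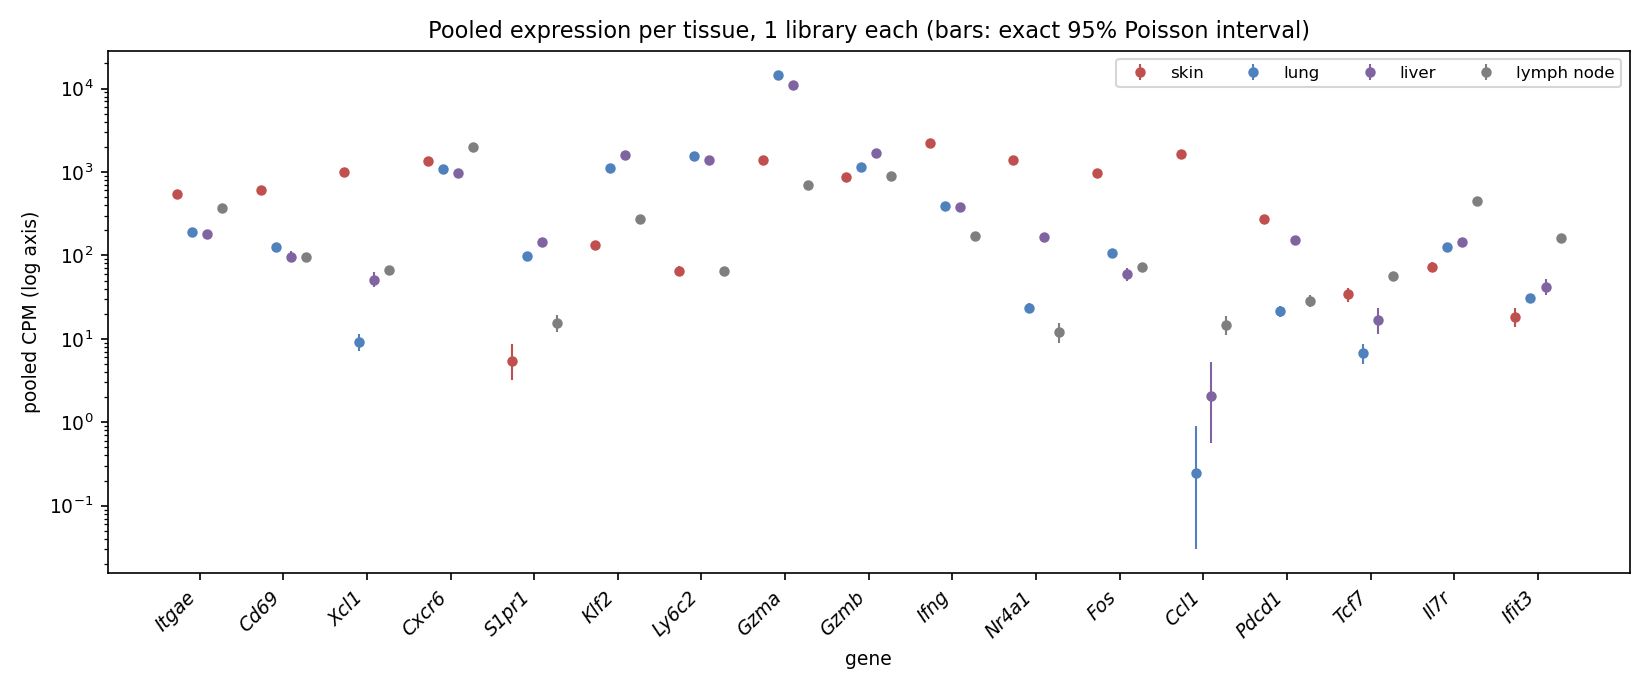
Pooled CPM (log axis) of selected genes of the lists in each tissue, with exact Poisson 95% intervals. Nr4a1 stands at 1395 CPM in skin and 11.9 in lymph node, and Klf2 at 1115 CPM in lung and 1616 in liver against 134 in skin.

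Between the peripheral tissues, skin held more of the residency genes than lung or liver did, and less of the recirculation genes. Against lung, 32 of 33 residency genes were higher in skin (median log2 ratio 1.80) and 15 of 20 recirculation genes were lower (-2.18). Against liver, 31 of 33 residency genes were higher (1.68) and 12 of 15 recirculation genes were lower (-1.98). Itgae was 2.84-fold higher in skin than in lung (2.65 to 3.04) and 3.03-fold higher than in liver (2.70 to 3.41). Xcl1 was 109-fold (86.7 to 140) and 19.3-fold (15.8 to 23.8) higher, and 67.8-fold and 11.9-fold without the 1 skin cell of highest count. Both comparisons ran across the difference in pseudogene counts.

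Against lung, skin was higher for 22 of 23 immediate early genes (median log2 ratio 2.42), 5 of 7 chemokine genes (2.57), 11 of 13 inhibitory receptor genes (1.76) and 12 of 13 TGF-beta response genes (1.76). All 14 genes of the TNF superfamily and costimulation were higher (1.48), as were 14 of 16 glycolysis genes (1.11), 11 of 12 heat shock genes (0.67), 9 of 12 identity genes (0.64) and 19 of 22 proliferation genes (0.54). Interferon stimulated genes were lower in skin for 18 of 21 (-0.78). Lipid genes were higher for 10 of 14 (0.54), receptors and integrins for 9 of 17 (0.25), cytotoxic genes for 9 of 19 (-0.07) and central memory genes for 5 of 13 (-0.15), all within the random range. Nr4a1 was 59.3-fold higher in skin (51.2 to 68.9), Sdc4 69.4-fold, Nfkbid 44.3-fold, and Tnfsf11, the gene of RANKL, 79.3-fold, or 159-fold without the lung cell that held 3 of its 6 counts there. AY036118, 59.0-fold higher, is uncertain. Ccl1 and Nr4a3 had 2 and 3 counts in lung, which gave ratios of 6690 (1851 to 55256) and 403 (137 to 1961). Lung was higher for Fcgrt (37.1-fold), Nccrp1 (36.1-fold), Nacc2 (33.1-fold), Gimap7 (32.5-fold), Tspan32 (27.0-fold), Ly6c2 (24.1-fold) and S1pr1 (18.2-fold, 11.4 to 30.8). Ggt1, with 2 counts in skin, had a ratio of 117 (32.3 to 969), and 234 without 1 of the 2 cells.

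Against liver, skin was higher for 22 of 23 immediate early genes (median log2 ratio 2.22), 12 of 13 TGF-beta response genes (1.39), 5 of 7 chemokine genes (1.34) and all 14 genes of the TNF superfamily and costimulation (1.14). It was also higher for 13 of 16 glycolysis genes (1.11) and 10 of 12 inhibitory receptor genes (0.82), and lower for 17 of 19 interferon stimulated genes (-1.05) and 10 of 17 receptors and integrins (-0.43). Identity (0.43), lipid (0.45), proliferation (0.31), heat shock (-0.0018), central memory (-0.03) and cytotoxic genes (-0.04) had medians within the random range. Ccl1 was 799-fold higher in skin (312 to 2934), or 1595-fold without the liver cell that held 2 of its 4 counts there. A skin cell with 1410 of the 5457 skin counts of Ccl1 stayed in both ratios, and leaving it out would lower them. Fosb was 38.3-fold, Sema6d 39.8-fold and Nfkbid 25.8-fold higher. Sdc4, with 2 counts in liver, had a ratio of 116 (31.9 to 961), and 231 without 1 of the 2 cells. Bcl2a1d, higher in skin by 22.5-fold, has near-identical copies and is uncertain, as is AY036118 (75.5-fold). Liver was higher for Gimap7 (30.7-fold), Fcgrt (30.1-fold), S1pr1 (26.3-fold, 16.3 to 45.0), Ly6c2 (21.5-fold), Tspan32 (17.0-fold), Rasa3 (13.4-fold) and Klf2 (12-fold, 10.9 to 13.3), and Ggt1, with 2 counts in skin, had a ratio of 105 (28.5 to 877), and 210 without 1 of the 2 cells.

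Lung and liver differed less, and their lowest list medians were those of inhibitory receptor and heat shock genes. Inhibitory receptor genes were lower in lung for 10 of 11 members (median log2 ratio -0.99) and heat shock genes for 12 of 12 (-0.76), both below every random list. Pdcd1 was 7.19-fold higher in liver (5.94 to 8.72), which may be a lower bound because its share of lung cells, 3.37%, lay below that of Lyz2 there. Ctla4 was 8.05-fold higher (6.60 to 9.84), Serpinb9 8.30-fold and Hilpda, a lipid droplet gene induced by hypoxia, 7.90-fold (6.77 to 9.23). Nr4a1 (7.09-fold), Crem (6.89-fold), Fosl2 (6.54-fold) and Tgif1 (5.53-fold) were also higher in liver. Those named as higher in lung were Hist1h1c (2.81-fold), Myadm (2.06-fold), Avl9 (1.91-fold), Arl4a (1.89-fold), Snrpa1 (1.88-fold), Fos (1.79-fold), Rbbp6 (1.77-fold) and Klf6 (1.59-fold). Lower in lung were 21 of 30 residency genes (-0.33), 17 of 22 proliferation genes (-0.27), 10 of 12 identity genes (-0.17) and 10 of 13 TNF superfamily genes (-0.23). So were 5 of 6 chemokine genes (-0.48), 14 of 21 interferon stimulated genes (-0.14) and 8 of 13 TGF-beta response genes (-0.20). With each gene's highest cell left out, the proliferation median was -0.11 and the chemokine median -0.28. Likewise the interferon median became -0.08 and the TGF-beta median -0.14. Both of these lay within the random ranges of the main values (-0.10 to 0.18 and -0.16 to 0.26). Recirculation (-0.05), central memory (-0.03), cytotoxic (0.06), receptor and integrin (0.07), immediate early (-0.04), lipid (-0.05) and glycolysis genes (0.01) had medians within the random range.

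In single cells, thinned to 1886 counts each, the shares of cells with residency and recirculation genes differed between tissues. Itgae was detected in 60.9% of skin cells (58.0 to 63.9), 28.9% of lung cells (27.0 to 31.0), 27.8% of liver cells (24.0 to 31.8) and 46.3% of lymph node cells (43.8 to 48.9). Unthinned, the shares were 71.7%, 44.1%, 42.4% and 59.7%. Cd69 was detected in 57.5%, 19.4%, 14.7% and 13.7% (unthinned 65.3%, 29.2%, 21.6% and 17.5%). Both genes together were detected in 35.1% of skin cells and in 5.86%, 4.35% and 6.89% of lung, liver and lymph node cells. Klf2 was detected in 16.8%, 78.6%, 84.1% and 22.3% (unthinned 20.2%, 88.2%, 91.5% and 26.3%), and S1pr1 in 1.20%, 17.8%, 21.9% and 2.21% (unthinned 1.39%, 28.1%, 36.0% and 3.88%).

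Gzma was detected in 27.9% of thinned skin cells, 91.5% of lung cells, 83.0% of liver cells and 19.4% of lymph node cells (unthinned 30.3%, 88.9%, 85.1% and 20.7%). Ifng was detected in 71.3%, 41.7%, 37.1% and 22.2% (unthinned 75.9%, 55.1%, 50.2% and 27.9%), and Pdcd1 in 27.6%, 3.37%, 23.3% and 4.89% (unthinned 30.9%, 6.46%, 32.4% and 6.95%). Cxcr6 was detected in 84.9%, 85.4%, 80.7% and 89.5% (unthinned 90.2%, 92.6%, 89.7% and 90.9%). Ccl1 was detected in 16.3% of skin cells and 0.0488%, 0.189% and 0.669% of the others, against 18.5%, 0.0431%, 0.540% and 0.677% unthinned. Genes of other cell classes were taken as the level of background, whose source was not tested. Lyz2, a myeloid gene, was detected in 5.37% of lung cells, 1.34% of lymph node cells and 0 cells of skin and liver, where a count of 0 allows up to 0.340% and 0.695%. Scgb1a1, of airway epithelium, was detected in 2.20% of lung, 2.08% of liver and 0 skin and lymph node cells, although liver holds no airway. Igkc, of B cells, was detected in 2.39% of lung, 1.87% of lymph node and 0.189% of liver cells. Igkc was detected in 0 skin cells, and the S1pr1 share of skin, 1.20% (0.641 to 2.04), lay above that. Background from the skin's own cells was not measured, so this does not show S1pr1 above background in skin. The S1pr1 share of lymph node, 2.21%, lay next to that of Igkc there. The Klrg1 share of lung, 1.90%, lay below that of Igkc there and is read as background. With lymph node cells clustered alone, the central memory-like cluster held all 8 measured naive or central memory markers above the other cells. S1pr1 is among these markers, so its lymph node counts are not background alone. Unthinned, S1pr1 was in 3.88% of lymph node cells (2.99 to 4.93) and Igkc in 2.65% (1.92 to 3.55), so the reading of S1pr1 depends on depth. Trdc, the constant gene of the delta receptor chain, was detected in 5.91% of skin, 0.537% of lung, 2.27% of liver and 8.63% of lymph node cells. The lung shares of Pdcd1, 3.37%, and Nr4a1, 4.20%, lay below that of Lyz2 there. After thinning, the cells of all tissues hold the same number of counts, but 160 of the 296 lung cells of cluster 6 were too shallow and left out. In pooled CPM, Klf2 was 1.69-fold (1.52 to 1.87) and Gzma 11.2-fold lower in these 296 cells than in the other lung cells.

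Clustering of all cells gave 9 clusters, and most of them followed the libraries. Cluster 3 held 94.0% of skin cells (1150 of 1224), cluster 2 held 80.4% of lymph node cells (1306 of 1625), cluster 5 held 60.4% of liver cells (336 of 556), and clusters 1, 4 and 6 held 55.5%, 27.2% and 12.7% of lung cells. The genes that defined these clusters included Nr4a1 and Ccl1 for cluster 3, Il7r and Lpar6 for cluster 2, Ctla4 and Serpinb9 for cluster 5, Klf2 and S1pr1 for cluster 1, Gzma and Gzmm for cluster 4, and Bcl2 and Trib3 for cluster 6. With 1 library per tissue, a cluster made mostly of 1 library may be that library and not a cell type. Cluster 1 also took 25.9% of liver cells. There, between 1288 lung and 144 liver cells, the residency list had a median log2 ratio of 0.00 for lung over liver and the recirculation list 0.03, both within the random range. Inhibitory receptor genes were lower in lung for 8 of 8 members (-0.88) and heat shock genes for 11 of 12 (-0.40), as over all cells, and immediate early genes were higher for 15 of 22 (0.41). Chemokine genes were higher in lung for 4 of 5 (0.38), the reverse of all cells, and central memory (-0.53) and TNF superfamily genes (-0.53) were lower, all 3 outside the random range.

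Clusters 1 to 5 held 5, 5, 7, 4 and 4 markers of resident or circulating effector memory cells above the other cells, and cluster 6 held 1. These 6 followed the libraries and are given by number, and the other 3 were named. Cluster 7 was interferon responding-like, with Rsad2, Ifit3, Usp18, Ifit1 and Isg15 among its leading genes, and held 8.12% of lymph node cells (6.84 to 9.56), 2.34% of liver, 1.21% of lung and 0.490% of skin cells. Cluster 8 was naive or central memory-like, with Lef1 and Ccr7 among its leading genes, and its 165 cells all came from the lymph node (10.2%, 8.73 to 11.7). Ahead of Lef1 came Izumo1r (296-fold), Wnt10a (104-fold), Cd200 (74.7-fold) and Tnfsf8 (62.0-fold), which are not among the markers behind the name. Cluster 9 was proliferating-like, with 8 of 8 markers above the other cells and Ccna2 among its leading genes, and held 3.43% of skin (2.48 to 4.61), 2.45% of lung, 3.06% of liver and 0.80% of lymph node cells (0.427 to 1.36). Since interferon stimulated, central memory and proliferation genes differed between the libraries, these shares describe the clusters and not the abundance of types.

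**Figure D4:**
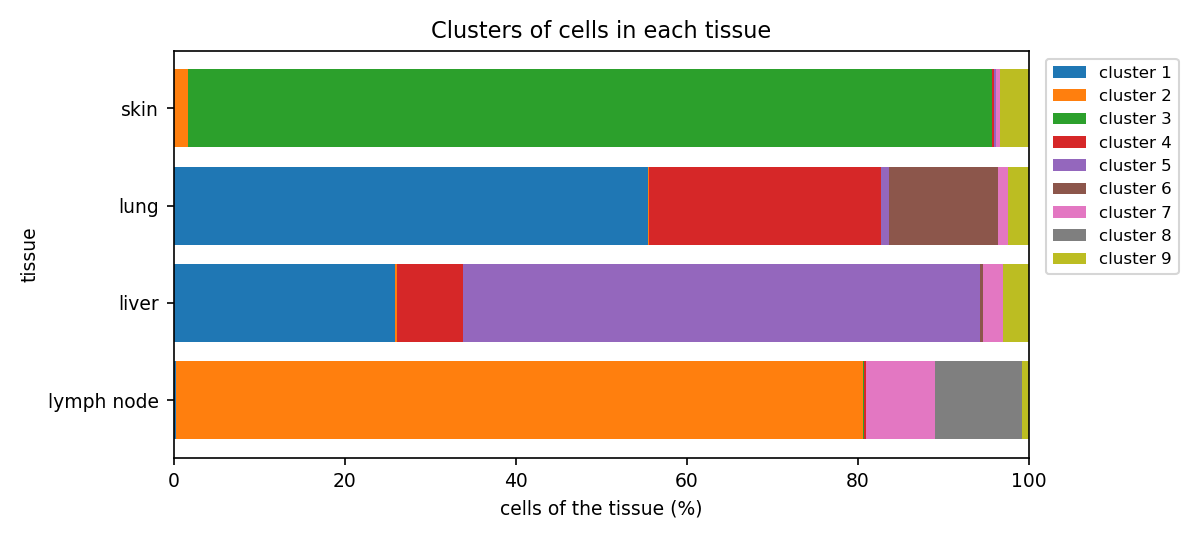
Percentage of each tissue's cells in each of 9 clusters (stacked bars, 1 library per tissue). Cluster 3 takes 94.0% of skin, cluster 2 takes 80.4% of lymph node, and cluster 1 is shared by lung (55.5%) and liver (25.9%).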

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

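Tests of pseudogene counts between libraries, of shared digestion, of a small subset of skin cells and of the skin digestion itself were chosen only after the result was seen. Lists whose median over the lymph node went one way in skin and the other way in lung or liver, both outside the range of random lists, drew a closer look. The difference itself was not tested, since each tissue has 1 library. The residency median log2 ratio was 0.66 in skin and -0.85 in lung. The recirculation median was -1.09 in skin, 0.47 in lung and 0.56 in liver. TGF-beta response genes stood at 0.79 in skin and -0.77 in lung. Genes of the TNF superfamily and costimulation stood at 0.33 in skin, -1.54 in lung and -1.04 in liver.

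Lung and liver libraries stood closest to each other, with a correlation of 0.965, and lymph node stood closer to lung, at 0.904, than to skin, at 0.886. Pseudogene counts relative to the parent gene differed by a median log2 of -1.89 for lung over lymph node and 0.44 for skin over lymph node, which is consistent with reads shared by gene copies having been counted differently in lung and liver. Predicted genes, pseudogenes, ribosomal, mitochondrial and receptor genes do not alone set lung and liver apart, because without them the lung and lymph node correlation was 0.905 and that of lung and liver 0.964. A difference between tissues stays open and cannot be told apart from one between libraries, since each tissue is 1 library. Without those genes skin and lymph node correlated at 0.882, below lung and lymph node.

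Immediate early genes were high in the skin library. Warm digestion with an equal effect in skin, lung and liver would give like medians in all 3. The median log2 ratio over lymph node was instead 0.44 in liver and 0.12 in lung against 2.73 in skin. Under size factors these were 0.87, 0.52 and 2.92. The protocols differed between these tissues, so a digestion effect of unequal size is not excluded. The signal did not come from a small subset, since 59.6% of thinned skin cells held Fos and 85.3% held Nr4a1. The digestion of the skin sample itself may have raised these genes, and heat shock genes, with a median log2 ratio of -0.0018 for skin over liver, do not decide it. It cannot be told apart from stimulation in the tissue, because skin and its protocol are the same sample, and the biological difference between tissues is untested.

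Recirculation genes were high in the lung and liver libraries. Of the 10 members at least 2-fold higher in lung, 0 had a pseudogene in the table, but the table holds only 14 with a parent, 12 of them of ribosomal protein genes, so that count decides nothing and shared reads stay open. A mixture of circulating and resident cells stays open too. Among thinned lung cells without a count of Klf2, 43.2% (38.5 to 47.9) held Itgae or Cd69, against 42.3% (39.9 to 44.8) of those with it, and these intervals overlap. A difference between the tissues is also open and untested.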

How the results depend on the processing

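Added after the data were seen were the alternatives on stimulated residency members, on central memory-like lymph node cells, on single cells of highest count and on predicted genes and pseudogenes. Of 198 alternative values, 119 stayed within the interval of the main value, 78 moved beyond it and 1 reversed. All 21 values with all deposited cells were the same, because the filter removed none, and all 21 without doublets stayed within the interval, as did all 9 with a pseudocount of 0.5. Immediate early medians kept their sign and moved in 5 of 24. In lung they became 0.52 under size factors, 0.34 as a mean over cells and 0.27 with counts of at least 100, and in liver 0.87 under size factors and 0.18 with such counts. No paired analysis was possible because each tissue has 1 library and no result comes from a test. Where a cause is not given, the cause was not tested. Depth limits the rarer genes, chiefly in liver, whose 1928185 counts were the fewest.

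Size factors from median ratios moved the median of all genes by 0.20 for skin, 0.40 for lung and 0.43 for liver over lymph node, and list medians by the same amount by construction. Residency became 0.86 in skin, -0.45 in lung and 0.0307 in liver, where the sign reversed, and recirculation -0.90, 0.87 and 0.996. Totals without the 50 highest genes gave residency -0.74 in lung. Members with a summed count of at least 100 gave residency 1.21 in skin, and recirculation -0.80 in skin, 1.16 in lung and 1.08 in liver. Without cells holding Mki67 or Top2a, recirculation was 0.76 in lung. Without members that stimulation raises, residency was 0.21 in skin, -0.97 in lung and -1.17 in liver. Without the central memory-like lymph node cells, residency was -0.98 in lung and recirculation -0.80 in skin, 0.87 in lung and 0.91 in liver. Without the skin cell of highest count, the Xcl1 ratio was 9.18 for skin over lymph node, 67.8 over lung and 11.9 over liver. Without such a lymph node cell, the Ccl1 ratio of skin over lymph node was 268. Leaving out the skin cell with 1410 of the 5457 Ccl1 counts instead would lower that ratio. The liver over lymph node ratio of Ccl3 was 1.27 without such a liver cell, and the other 6 ratios stayed within their intervals. With each member's highest cell left out, chemokine medians became 2.13 for skin over lung and 1.67 for skin over liver. The proliferation median of lung over liver became -0.11, and the other 9 medians of these lists stayed. Medians of the remaining lists were not set against an interval in this way. Recirculation for skin over lymph node went from -1.09 to -1.28. For lung over liver, interferon stimulated genes went from -0.14 to -0.08 and TGF-beta response genes from -0.20 to -0.14.

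Shares of cells depend on depth by construction, and values follow in the order skin, lung, liver and lymph node. Unthinned, Itgae was in 71.7%, 44.1%, 42.4% and 59.7%, Cd69 in 65.3%, 29.2%, 21.6% and 17.5%, and S1pr1 in 28.1% of lung, 36.0% of liver and 3.88% of lymph node cells. Thinned to 2277 counts, Itgae was in 67.9%, 35.3%, 33.4% and 54.9%, Cd69 in 62.6% of skin and 21.3% of lung cells, and S1pr1 in 20.6% of lung, 26.5% of liver and 3.20% of lymph node cells. With at least 2 counts per cell, Itgae was in 40.5%, 15.6%, 14.4% and 28.0%, Cd69 in 39.5%, 9.30%, 6.29% and 5.35%, and S1pr1 in 0.0817%, 5.60%, 9.35% and 0.431%.

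The largest cluster of lung held 85.8% at resolution 0.3, 46.6% at resolution 1.0 and 51.3% with another seed. That of liver held 96.0% at resolution 0.3 and 82.2% without immediate early and heat shock genes, and that of lymph node 88.4% at resolution 0.3. Correlations over genes with at least 50 CPM were 0.743 for skin and lung, 0.784 for skin and liver, 0.813 for skin and lymph node, 0.954 for lung and liver, 0.842 for lung and lymph node and 0.817 for liver and lymph node. Without predicted genes, pseudogenes, ribosomal, mitochondrial and receptor genes, they were 0.856 for skin and lung, 0.872 for skin and liver and 0.882 for skin and lymph node.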

Other observations

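The clustering of lymph node cells alone, the description of a lung cluster and the look at cytokine-positive skin cells were chosen only after the data were seen. Lymph node cells were clustered without 75 genes, those of the residency, recirculation and central memory lists and the markers of naive or central memory, resident, circulating effector and exhausted cells. Of 1625 cells, 167 formed a central memory-like cluster apart from the 1339 cells of the main cluster, and 163 of them belonged to cluster 8 of the joint clustering. Left out of the clustering, the central memory list was higher in these 167 cells for 12 of 14 members (median log2 ratio 2.03) and the recirculation list for 13 of 18 (0.54). The residency list was lower for 21 of 32 (-0.96). Slamf6, a marker of stem-like cells, was 23.1-fold higher in them (15.7 to 34.6), Klf2 4.59-fold (4.06 to 5.20) and Tcf7 3.96-fold (2.99 to 5.20). Cxcr6 was lower, at 221 CPM against 2205, and Itgae 4.57-fold lower (3.33 to 6.45). Inhibitory receptor genes, of which 7 of 13 in the table were left out of the clustering and 6 took part, were higher for 9 of 12 measured (1.86). A smaller cluster of 119 cells held interferon stimulated genes (21 of 21 higher, 2.21) and proliferation genes (20 of 20 higher, 2.55), both used in the clustering. In the joint clustering 84 of them belonged to cluster 7, 18 to cluster 2 and 13 to cluster 9, so the lists may be high in different cells.

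In lung, 296 cells formed cluster 6, which took only 2 liver cells. They held fewer counts, with a median of 1850 against 3144 in other lung cells, a mitochondrial share of 1.62% against 1.88%, and 0 doublets. Trib3 (31.6-fold, 18.2 to 57.1), Atf5 (15.7-fold), Asns (14.5-fold), Mthfd2 (6.14-fold) and Ddit3 (5.14-fold) were higher in them. The intervals of Psat1 (0.531 to 2.15, other lung cells over cluster 6), Sesn2 (2.26-fold, 0.424 to 7.80) and Hspa5 (1.10-fold, 0.957 to 1.27) held equality, and Malat1 was higher, at 29187 CPM against 14881. Bcl2, which encodes a survival protein, was 26.2-fold higher (21.1 to 32.6), Slc7a5, an amino acid transporter gene, 18.5-fold, and Lta, the gene of lymphotoxin alpha, 15.6-fold. Gzma was 11.2-fold lower (10.5 to 12), Ly6c2 6.15-fold, S1pr1 5.15-fold, Ccl5 3.69-fold and Gzmb 2.45-fold, while Cd3e and Trbc2 differed by 1.14-fold and 1.10-fold. These genes helped to define the cluster, and the genes were chosen after their values were seen.

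Counts of Ccl1 and Xcl1 in skin were concentrated in few cells. Ccl1 was detected in 18.5% of 1224 skin cells, and the top 10% of cells held 98.1% of its 5457 counts, with 1410 in a single cell. The corresponding figures were 93.4% of counts for Xcl1, with 1241 of 3254 in a single cell, 59.6% for Ifng, detected in 75.9% of cells, and 30.6% for Nr4a1. Among thinned skin cells, Xcl1 was detected in 39.2% of cells with Ccl1 (31.9 to 46.8) and 17.9% of those without (15.4 to 20.5). Il13 and Areg, genes linked to type 2 immunity and tissue repair, stood at 53.8 CPM and 71.4 CPM in skin. In lung, liver and lymph node, Il13 stood at 0.991, 1.56 and 0 CPM, and Areg at 0.619, 0.519 and 0.883 CPM. Both are among the fixed markers of type 2 innate lymphoid cells, and all 4 measured markers of these cells were higher in skin than in lymph node (median log2 ratio 3.62, above every random list). Cd8a was detected in 88.5% of cells with Il13 (77.8 to 95.3) and 90.5% of those without, in 86.5% of cells with Areg, and Trbc2 in all of these. Cd3e was detected in 72.1% of cells with Il13 (59.2 to 82.9) and 82.9% of those without (80.4 to 85.1).

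Markers of neutrophils, mast cells, melanocytes, fibroblasts and erythrocytes were not in the table, with 0 members each, so those cells were not assessed. CD4 or regulatory T, gamma delta T and NK cells and keratinocytes had 2 markers each in the table. Plasma, Kupffer, endothelial, lung epithelial and liver sinusoid or stellate cells and hepatocytes had 1 each. These were too few for a cluster to be called by them, so such cells are not excluded. Trbv14 was the only beta chain variable segment in the table (chromosome 6, 41135145 to 41135616). It stood at 123 CPM in skin, 38.6 in lymph node, 6.07 in lung and 5.19 in liver. Its levels thus split the libraries as the pseudogene counts did, and skin and lymph node also differed.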
